A study of Mus musculus with 4 samples.

How the data were processed

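RNA was measured on Affymetrix Mouse Gene ST arrays in cells taken by laser capture microdissection from the stomach of adult mice, per the labels and the series design text. Laser capture cuts chosen cells out of a tissue section under the microscope. The study covered 2 cell types, mucous neck cells and zymogenic (chief) cells, in wild-type mice and in mice lacking MIST1, a transcription factor of secretory cells encoded by Bhlha15. Each of the 4 groups was 1 array. Per the labels' protocols, RNA was pooled over several dissections and several mice to about 100 ng before amplification, and the mice had a C57BL/6 background. The design text gives 4 wild-type and 5 MIST1-null mice with 2 caps per mouse. Which of these animals entered which pool is not given in the sources used here. Zymogenic cells were picked as gland cells lying basal to the lectin GS-II signal and lacking the outline of parietal cells in dehydrated sections. The lectin marks neck cell mucus, so genes of that mucus stand close to the choice of the cells. Per the design text, RNA was treated with DNase I, and the arrays were checked and compared in the program dChip.

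The deposited values were probe set intensity values on a linear scale, from 0.86 to 14251, and the authors made them with dChip per the series design text. The background correction, the summary over probes and the scaling are not given in the sources used here. The medians of the 4 arrays lay close together, at 39.3 for wild-type neck, 37.9 for MIST1-null neck, 40.9 for wild-type zymogenic and 39.6 for MIST1-null zymogenic cells. The upper and lower quartiles differed between arrays, so the probe set values themselves had not been quantile normalized. A normalization of single probes before their summary is not excluded by this. Signal over background is unknown, since no detection calls were used here, and the number of arrays limits the precision.

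Of 35512 probe sets, 21789 had exactly 1 gene in the platform annotation, 1621 had several and 12102 were not listed there. Only the first kind entered the comparisons, and no gene was named from a probe set with several. The Entrez identifiers of 21698 probe sets were matched to RefSeq genes of assembly GRCm38.p6, which changed 0 symbols. That table was used for names, for the chromosome of a gene and for the order of neighbouring genes. A gene with several probe sets was represented by the one with the highest mean, which left 19938 genes, 999 of them with more than 1 probe set. Values were taken as log2 with a floor at an intensity of 1, and 40 to 48 values per array lay at or under it. In each comparison a gene counted as detectable where the higher of its 2 values reached the median of all 1-gene probe sets, a log2 value of 5.45. This level is a rule of size and not a measured background.

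With 1 array per group, no difference between 2 arrays has a replicate check and no p-value is given for one. Differences are log2 values, written as MIST1-null minus wild-type and as zymogenic minus neck, and genes were counted at 2-fold or more. The genotype differences in both cell types rest on separate arrays, as do the cell type differences in both genotypes, and were set against each other with the overlap of independent lists. Shares carry exact Clopper-Pearson intervals at 95%, which cover counting error only. Genes named by rule were the 10 largest differences each way per comparison among genes reaching the 75th percentile, a log2 value of 6.34, without predicted, olfactory, vomeronasal and small RNA symbols. For both cell types together, the 10 genes with the largest smaller difference each way were named. Bhlha15 was always reported, outside these rankings. Members of fixed lists served as examples of their list. The rules, the fixed lists and the alternatives were set before the data were examined.

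The fixed lists were zymogenic cell products, mucous neck, surface mucous, parietal, endocrine, fibroblast and smooth muscle, immune and endothelial cell markers, red blood cell genes, pancreatic acinar enzymes, cell cycle genes, reported MIST1-activated genes, regulated exocytosis genes, ER chaperone and unfolded protein response genes, lysosome genes, metaplasia-associated genes, Notch pathway genes, oxidative phosphorylation genes, cytosolic ribosomal protein genes, immediate early and heat shock genes, interferon response genes, cholesterol synthesis genes, and Y-linked genes with Xist, read gene by gene. The MIST1-activated genes were recalled from earlier work on secretory cells and not checked here. The median difference over the detectable members of a list was set against 10000 random lists of the same size matched on mean expression in 20 bins. A list was called apart from random lists below the 2.5th or above the 97.5th percentile, and at least 3 detectable members were needed. By chance about 1.05 of 21 lists would be called in a comparison if the genes of a list moved independently. Genes of 1 cell type or pathway can move together, and this number does not cover that. These percentiles describe the 4 arrays only. A list of mitochondrial matrix and stimulus receptor genes of parietal cells and a list of squamous keratinocyte genes were added after the data were seen.

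A secondary model fitted genotype and cell type as additive terms over all 4 arrays with limma (lmFit and eBayes with a trend), with 1 residual degree of freedom and Benjamini-Hochberg adjustment at 0.05. It takes any difference between the genotype effects of the cell types as error. Alternatives were quantile normalization, cyclic loess, median centring, no filter on low values, a filter at the 75th percentile, a 3-fold threshold, a pseudocount of 32, the mean over a gene's probe sets, and limma without the trend.

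The steps were tested on simulated data for the genotype comparison in zymogenic cells, with 11455 detectable genes and noise of 0.34 log2 units per array, taken from the spread of the quieter neck pair. Of 50 genes changed 2-fold, 62% passed the 2-fold threshold, and of 50 genes changed 4-fold, 100% did. At that noise, 5.03% of unchanged genes passed it, and 0.11% passed it the same way in both cell types. At the zymogenic pair's own spread, 0.46 per array, 16.1% of unchanged genes and 48% of genes changed 2-fold passed it among 11848 genes. In neck cells, at their own spread, 4.84% and 40% did among 11454 genes. These spreads hold any effect of genotype as well, so they overstate the noise. At the neck pair's noise, the limma model called 34% of the genes changed 2-fold and 100% of those changed 4-fold. Each simulated change was the same in both cell types, and the noise was equal for all genes. The additive model thus held by construction, and these shares do not carry over to the data, where unequal genotype effects count as error. A list of 12 genes shifted by 0.5 reached percentile 99.8, and 5 of 100 unshifted lists were called apart. The simulated genes varied independently, so this rate does not cover lists whose genes move together. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1, were used.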

Results

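Gene expression was measured in mucous neck cells and zymogenic cells of the gastric corpus, cut by laser capture from wild-type and MIST1-null mice. Neck cells secrete mucus in the middle of the gland and are held to be the source of zymogenic cells, which sit at the gland base and store digestive enzymes. The design asks how the cell types differ and what the loss of MIST1 alters in each. There was 1 array per group, so none of the differences below has a replicate check, and levels are array intensities.

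Bhlha15, the gene of MIST1, had its highest intensity in wild-type zymogenic cells, at 149.8, against 59.7 in wild-type neck cells. In MIST1-null mice it read 22 in zymogenic and 20.2 in neck cells, both under the detection level. The differences were -2.77 in zymogenic and -1.56 in neck cells on the log2 scale, sizes that are not firm at such low values. With the pseudocount of 32 they were -1.75 and -0.81, the latter under 2-fold. Among the 1000 genes closest in mean expression, 1 had as low a difference in zymogenic cells and 6 in neck cells, or 0 and 9 with the pseudocount. The array labels and the targeted gene thus run the same way, although the position of its probes relative to the deleted part is not given in the sources used here.

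**Figure D1:**
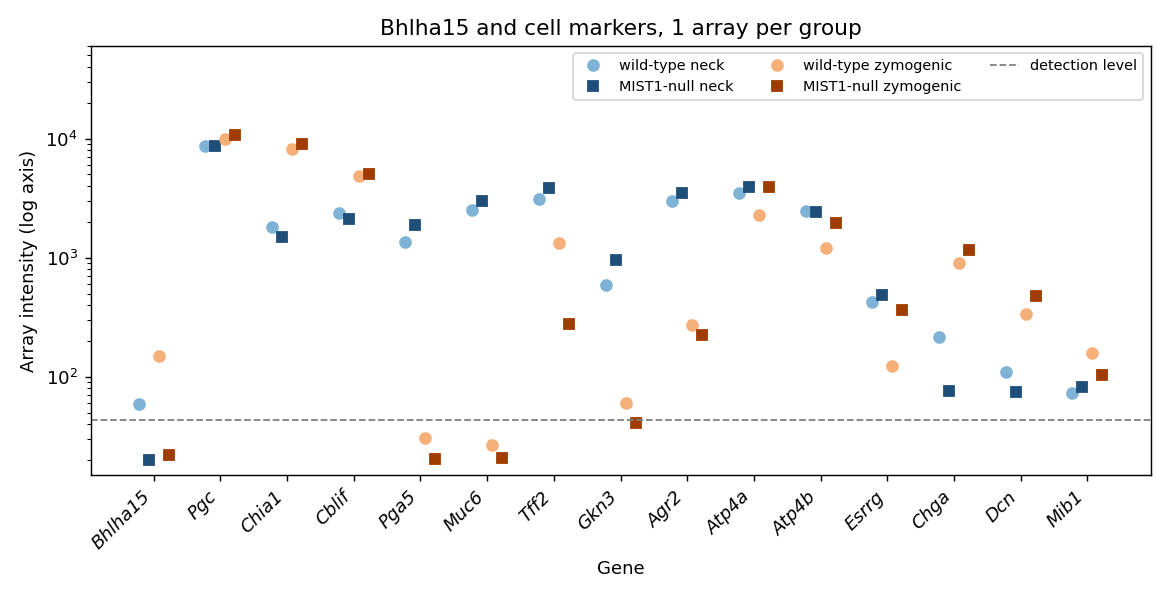
Array intensity (log axis) of Bhlha15 and 14 marker genes, with 1 point per array and the detection level dashed. Muc6 lies near 2511 and 2980 in neck cells and near 26.7 and 20.7 in zymogenic cells, while Bhlha15 lies under the detection level in both MIST1-null arrays.

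In wild-type mice, mucus genes were far lower in zymogenic than in neck cells. Muc6, the gland mucin, was lower by a log2 difference of -6.56, at an intensity of 26.7 against 2511. The lower value is under the detection level, so the size is not firm, and it was -5.44 with the pseudocount of 32. Of 6 mucous neck cell markers, 5 were at least 2-fold lower in zymogenic cells and the list median was -2.94, at percentile 0 of matched random lists. Agr2, a folding enzyme for mucins, differed by -3.45, Gkn3 by -3.31, A4gnt, which caps gland mucin sugars, by -2.57 and the trefoil peptide Tff2 by -1.23, while the water channel Aqp5 differed by 0.54. Zymogenic cell products had a median of 0.62 over 4 detectable members, at percentile 98.6.

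The zymogenic products did not move as 1 block. The acidic chitinase Chia1 was higher in wild-type zymogenic cells by 2.18 and Cblif, gastric intrinsic factor, by 1.04. The pepsinogen gene Pgc was near the top of the range in every array, from 8672 to 10638, and differed by 0.20. Another pepsinogen gene, Pga5, went the other way by -5.45, with 1350 in neck and 31.0 in zymogenic cells, the latter also under the detection level, and by -4.46 with the pseudocount. Cym and Lipf were under the detection level in all 4 arrays.

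Among the genes named by rule, those furthest up in wild-type zymogenic over neck cells were the homeobox gene Msx2 (3.67), Gdf9 (3.62), a growth factor best known from oocytes, Aldh1a7 (3.55), Chil5 (3.36), the protease inhibitor Serpina3n (3.32), the helicase gene Blm (3.25), the amino acid carrier Slc7a5 (3.17), Tppp3 (3.17), the trypsin inhibitor Spink1 (3.04) and Sostdc1 (3.04). Furthest down after Muc6 and Pga5 were Fam3c (-5.16), the complement factor Cfi (-5.14), the mitotic kinase Plk1 (-4.83), Galntl6 (-4.79), the ER-bound transcription factor Creb3l4 (-4.72), Oit1 (-4.56), the fatty acid binding protein Fabp1 (-3.88) and Rassf10 (-3.88). Most of these genes read under the detection level in the lower array, so order and size are not firm. With the pseudocount of 32, 7 of 10 were again among the furthest each way. In all, 739 genes were at least 2-fold higher and 799 at least 2-fold lower of 11778 detectable genes, which together made 13.1%.

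ER chaperone and unfolded protein response genes, which serve protein folding for secretion, were higher in wild-type zymogenic cells, with a median of 0.48 at percentile 100 and 20 of 24 members above 0. Creld2 differed by 1.60, the translocon subunit Sec61b by 1.28 and Dnajc3 by 1.06, and Pdia3 by -0.74. The reported MIST1-activated genes had a median of 0.89 at percentile 98.4, with 4 of 4 detectable members above 0, among them the ubiquitin ligase gene Mib1 at 1.12. Pancreatic acinar enzymes had a median of 0.56 at percentile 99.0. Spink1 belongs to that list, and Clps, colipase, was at 9327 or above in both wild-type arrays with a difference of 0.20.

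Markers of other cells also moved with cell type in wild-type mice. Parietal cell markers, from the acid-secreting cells, were lower in zymogenic cells with a median of -1.10 at percentile 0 and 13 of 13 below 0, and oxidative phosphorylation genes had a median of -0.52 at percentile 0.225. Higher in zymogenic cells were endocrine markers (median 0.86, percentile 99.99), fibroblast and smooth muscle markers (1.09, percentile 100) and immune markers (0.90, percentile 99.9). Chgb differed by 2.44, the smooth muscle actin Acta2 by 2.17 and Lyz2 by 2.49. Cholesterol synthesis genes had a median of -0.47 at percentile 2.03, with Sqle at -1.79. Surface mucous markers (0.35), cell cycle genes (-0.37), metaplasia-associated genes (-0.59) and the remaining lists stayed within random lists, with 11 of 21 lists apart. With no filter on low values, the zymogenic products and the cholesterol genes also came within them, the latter also with the 75th percentile filter, at percentile 4.05. Calls were gained by surface mucous markers under quantile normalization (percentile 97.7) and the 75th percentile filter (97.6), and by cell cycle genes with that filter (2.24). Metaplasia genes gained theirs with no filter (1.09), the 75th percentile filter (0.575) and the pseudocount (0.84).

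In MIST1-null mice, Muc6 and Pga5 were again furthest down in zymogenic against neck cells. Muc6 differed by -7.17 and Pga5 by -6.53, followed by Oit1 (-5.58), Plk1 (-5.47), Galntl6 (-5.07), Fam3c (-4.76), Rassf10 (-4.75), Creb3l4 (-4.69), Gkn3 (-4.57) and the mitotic spindle gene Ckap2 (-4.30). The neck marker list had a median of -3.94 at percentile 0, and zymogenic products had 0.77 at percentile 99.6, with Chia1 at 2.59 and Cblif at 1.25. The genes furthest up were Lgals7 (6.05), Sostdc1 (4.56), the granins Chgb (4.16) and Chga (3.93), Fam166b (4.15), S100a4 (4.01), vitronectin, Vtn (3.85), Cyp1b1 (3.82), the smooth muscle calponin Cnn1 (3.60) and Serpina7 (3.57). Most of these genes read under the detection level in the lower array, and 5 of 10 each way stayed among the furthest with the pseudocount. Lgals7 was then at 3.20, Fam166b at 1.69, Sostdc1 at 3.79, Chgb at 3.78 and Chga at 3.47. At least 2-fold higher were 555 genes and 543 were lower, of 11322 detectable, or 9.70%.

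Several of those highest genes belong to endocrine or stromal cells, and those lists were again apart. Endocrine markers had a median of 1.87 and fibroblast and smooth muscle markers 1.89, both at percentile 100, and immune markers had 1.28 at percentile 100. Surface mucous markers (0.71, percentile 99.98), interferon response genes (1.21, percentile 99.7) and ER chaperone genes (0.61, percentile 100) also lay above. Below lay cell cycle genes (-0.97, percentile 0), metaplasia-associated genes (-0.66, percentile 0.3) and cholesterol synthesis genes (-0.41, percentile 0.61). Parietal markers were at -0.22 and oxidative phosphorylation genes at -0.11 in this contrast, and the MIST1-activated genes at -0.16, all within random lists. Pancreatic acinar enzymes (0.50) were within them too, but apart under quantile normalization (percentile 98.6), cyclic loess (98.6), no filter (97.9) and the pseudocount (99.9). With no filter on low values, the zymogenic products and the metaplasia, interferon and cholesterol lists lost their calls, as did immune markers and cholesterol genes with the 75th percentile filter. Ribosomal protein genes (-0.23) gained a call with that filter, and immediate early and heat shock genes (0.63) under median centring.

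**Figure D2:**
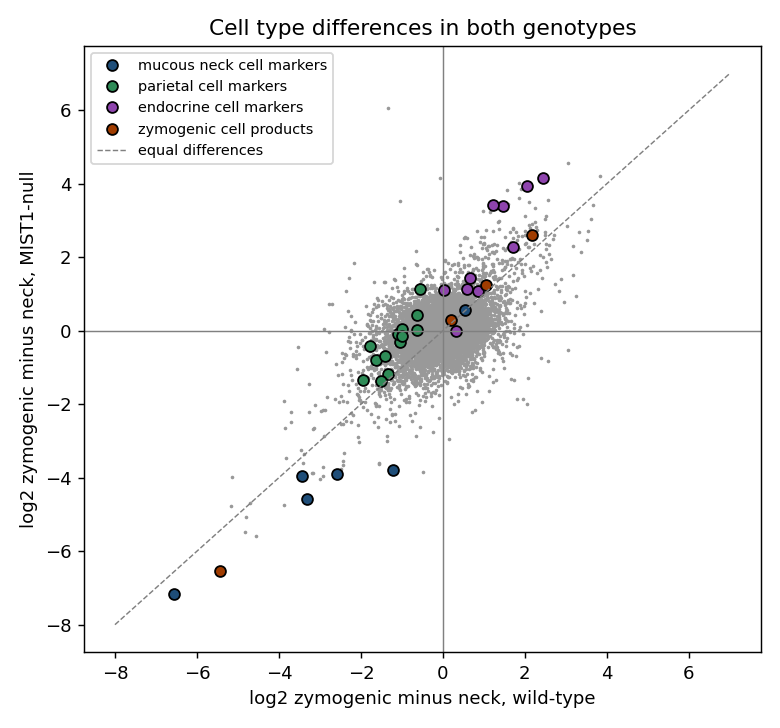
Each grey point is a gene detectable in both genotypes, at its log2 difference of zymogenic minus neck cells in wild-type mice (horizontal) and MIST1-null mice (vertical), with members of 4 marker lists coloured and equal differences dashed. Muc6, Pga5 and other neck genes lie far down in both, endocrine markers other than Gast lie above the dashed line, and the list median of parietal markers was -1.10 in wild-type and -0.22 in MIST1-null mice.

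The cell type differences of both genotypes were related across genes. Of genes detectable in both, 188 were at least 2-fold higher in zymogenic cells of both genotypes where independent lists would share 21.0, and 206 were lower where they would share 32.2. Pearson's r was 0.49 across 10165 genes, which are not independent replicates. Of the 739 zymogenic-enriched genes of wild-type mice, 206 kept a 2-fold difference in MIST1-null mice, or 27.9% (95% CI 24.7 to 31.3), and their median went from 1.32 to 0.44. Of the 799 neck-enriched genes, 210 kept it, or 26.3% (23.3 to 29.5). Genes picked on 1 contrast shrink in the other by chance, and the shares the other way round, chosen in MIST1-null and read in wild-type mice, were 35.1% for zymogenic-enriched and 40.1% for neck-enriched genes.

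In zymogenic cells, loss of MIST1 came with lower levels of Spink1 (-3.14, from 319 to 36.1) and of the mucosal trefoil peptide Tff2 (-2.25, from 1320 to 277). Furthest down among the genes named by rule were Tmem196 (-4.32), the RNA polymerase subunit gene Polr2j (-4.18), Pik3r5, a regulatory subunit of a lipid kinase (-4.08), the ciliary gene Hyls1 (-3.72), Nsun7 (-3.50), the SNARE-binding Stxbp6 (-3.30), the lysine catabolic enzyme Aass (-3.26), Gtf2ird1 (-3.24), Spink1 and Tmem19 (-3.13). Furthest up were Tmem50b (3.30), the cytokine receptor-like Crlf3 (3.05), Ppargc1a (2.71), a coactivator of mitochondrial genes, Lgals7 (2.65), a galectin of stratified epithelia, Tmx2 (2.65), Nme6 (2.63), Lce3a (2.59), the peptidase Erap1 (2.55), the mitochondrial iron carrier Slc25a37 (from 25.8 to 146) and the sialyltransferase St6gal1 (from 15.0 to 84.9). All 10 lowest genes and most of the highest read under the detection level in the lower array, so order and size are not firm. With the pseudocount of 32, 7 of the lowest and 6 of the highest stayed among the furthest 10, with Tmem196 at -2.09, Polr2j at -3.36 and Pik3r5 at -2.42. Counts were 609 genes at least 2-fold higher and 619 lower of 11826 detectable, or 10.4%. Of unchanged simulated genes, 5.03% passed 2-fold at the neck pair's noise and 16.1% with the whole spread of this pair as noise. That whole spread was taken from these same differences, so the 16.1% could hardly fall under the observed share and cannot judge it. With 1 array per group, the count is not a number of genes altered by loss of MIST1.

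The digestive products differed little between genotypes in zymogenic cells, with the limit that Pgc and Chia1 lay near the top of the arrays' range, where a difference can be hidden. Pgc differed by 0.09, Chia1 by 0.14 and Cblif by 0.04, and the list median of 0.09 was within random lists. Mucous neck markers were lower in MIST1-null zymogenic cells, with a median of -0.56 at percentile 0.675 and 5 of 5 detectable members below 0. ER chaperone genes were higher, with a median of 0.45 at percentile 99.7 and 17 of 24 above 0. Edem1 differed by 0.95, Canx by 0.70, Hspa5 by 0.46 and the translocon subunit Sec61b by -0.87. The 4 detectable MIST1-activated genes were all below 0, at -0.88 for Ccpg1, -0.68 for the connexin Gjb1, -0.60 for Mib1 and -0.46 for Rab26. Their median of -0.64 lay at percentile 4.46, within random lists, but at 0.94, apart from them, with no filter on low values. Rab3d, a granule GTPase, was under the detection level in all 4 arrays.

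Parietal cell markers were higher in MIST1-null zymogenic cells, with a median of 0.99 at percentile 100 and 13 of 13 detectable members above 0. The proton pump subunits Atp4a and Atp4b differed by 0.80 and 0.69, Kcne2 by 1.05 and Esrrg by 1.56. Oxidative phosphorylation genes moved with them, with a median of 0.50 at percentile 99.5 and 15 of 15 above 0. The wild-type zymogenic array was the lowest of the 4 for Atp4a, Atp4b, Kcne2 and Esrrg, with Atp4b at 1202 against 1945 to 2484 in the others. Metaplasia-associated genes, linked to a mucous change of the injured stomach, had a median of 0.66 at percentile 98.9 over 4 detectable members, with Dmbt1 at 1.46 and Clu at 0.76. Cytosolic ribosomal protein genes had a median of -0.14 at percentile 1.84. The metaplasia and ribosomal calls were lost with no filter on low values, and the metaplasia and neck marker calls with the 75th percentile filter, the latter also with the pseudocount of 32.

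Lists within random lists in this comparison were surface mucous (0.37), endocrine (0.37), fibroblast and smooth muscle (0.43), immune (-0.23) and endothelial (0.09) markers, pancreatic enzymes (-0.07), cell cycle (-0.16), exocytosis (0.01), lysosome (0.27), Notch (-0.34), immediate early (0.24), interferon (0.21) and cholesterol (0.05) genes. Cell cycle genes were apart with no filter on low values, with a median of -0.37 at percentile 0.53. Red blood cell genes had no detectable member.

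**Figure D3:**
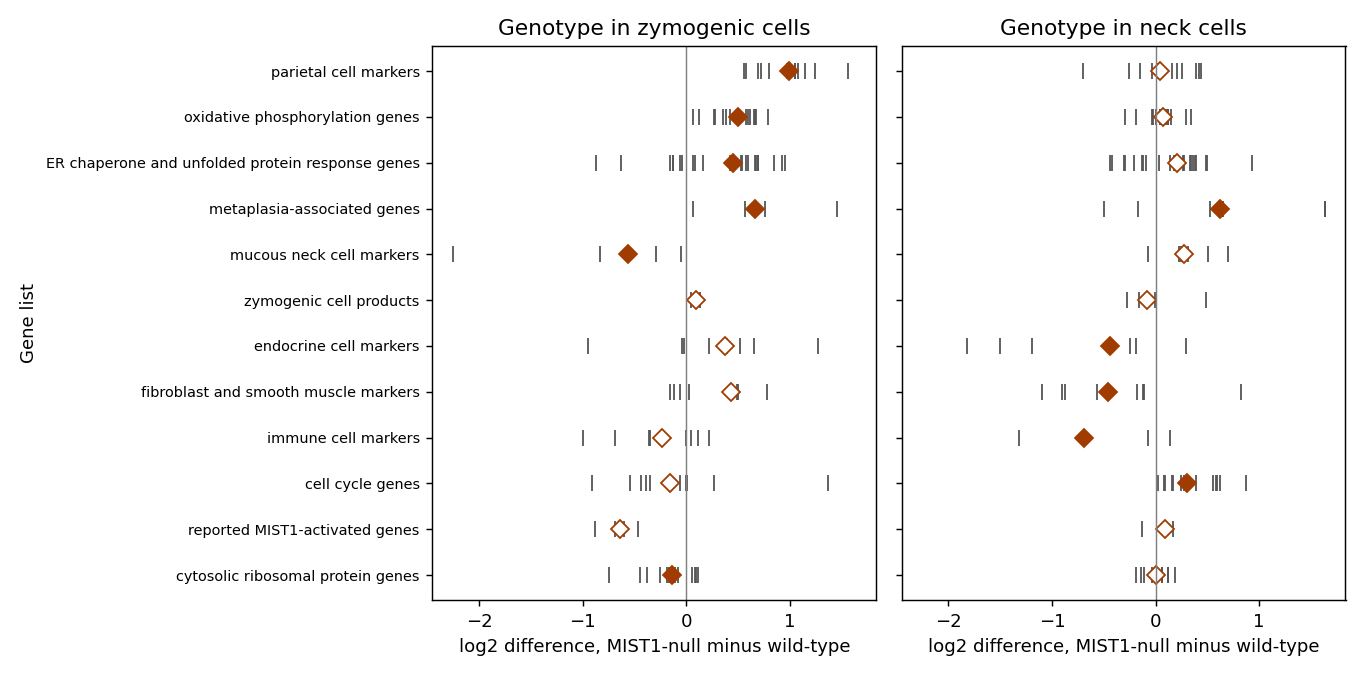
Log2 difference of MIST1-null minus wild-type arrays for the detectable members (ticks) of 12 gene lists in zymogenic cells (left) and neck cells (right), with list medians as diamonds, filled where the list was apart from matched random lists. Parietal markers have a median of 0.99 in zymogenic and 0.04 in neck cells, and metaplasia-associated genes are filled on both sides, at 0.66 and 0.62.

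In neck cells, fewer genes passed 2-fold between genotypes, with 207 higher and 263 lower of 10966 detectable, or 4.29%. In simulated data with the whole spread of this pair as noise, 4.84% of unchanged genes passed it. That spread was taken from these same differences, so a like share follows largely by construction and cannot judge the count. With 1 array per group, the count is not a number of genes altered by genotype. Furthest up in MIST1-null neck cells were Fam185a (2.86), N4bp2 (2.59), the ciliary gene Ttc8 (2.43), Myef2 (2.34), the interferon receptor chain Ifnar2 (1.86), Thap6 (1.79), Casp8ap2 (1.73), the chromatin remodeller Hells (1.66), Mfsd1 (1.64) and Trmt10b (1.64). Furthest down were Lgals7 (-4.73), the leukocyte tetraspanin Cd53 (-4.22), Pik3r5 (-3.53), Tmem19 (-2.66), Sharpin (-2.43), Mr1 (-2.21), Psg26 (-2.10), Fez1 (-2.10), BC002059 (-2.05) and Mfsd8 (-2.02). All of these falls but Sharpin and BC002059 read under the detection level in the MIST1-null neck array. Among the rises, Fam185a, Ttc8, Myef2, Casp8ap2, Hells and Trmt10b read under it in the wild-type neck array. Lgals7, Cd53 and Pik3r5 were at -2.07, -1.97 and -1.77 with the pseudocount of 32. Of the furthest genes, 6 of 10 each way were shared with that choice, so order and size are not firm. The pair of neck arrays had the smallest spread of any pair, with an SD of 0.48 over log2 differences against 0.65 for the zymogenic pair.

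Metaplasia-associated genes were higher in MIST1-null neck cells too, with a median of 0.62 at percentile 99.9. Wfdc2 differed by 1.64, from 119 to 369, the secreted glycoprotein Olfm4 by 1.63, Sox9 by 0.62 and Clu by 0.53, while Gpx2 and Muc4 differed by -0.50 and -0.17. Cell cycle genes were higher, with a median of 0.30 at percentile 98.8 and 15 of 15 detectable members above 0, none of them by 2-fold. Mcm7 differed by 0.87, Bub1 by 0.63 and Mcm6 by 0.60. Neck markers had a median of 0.28 and ER chaperone genes 0.20, both within random lists, as were zymogenic products (-0.08) and MIST1-activated genes (0.09). The ER chaperone genes were apart under median centring and with the pseudocount, the latter at percentile 98.2.

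Markers of some other cells were lower in the MIST1-null neck array, while surface mucous and parietal markers were not. Endocrine markers had a median of -0.44 at percentile 0.16, fibroblast and smooth muscle markers -0.46 at percentile 0.32, immune markers -0.69 at percentile 0.21 and pancreatic enzymes -0.48 at percentile 0.53. Somatostatin, Sst, differed by -1.82, Chga by -1.51, Vim by -1.10, H2-Aa by -1.32 and Pnliprp1 by -2.01. The immune and pancreatic calls were lost with no filter on low values. Within random lists were surface mucous (0.04) and parietal (0.04) markers, oxidative phosphorylation (0.07), ribosomal (0.00), exocytosis (0.13), lysosome (0.16), Notch (-0.21), immediate early (-0.03), interferon (-0.15) and cholesterol (0.26) genes. Of these, cholesterol genes were apart with no filter (percentile 98.2) and the pseudocount (98.0), and Notch genes with the mean of probe sets (-0.39, percentile 1.87). Endothelial markers had 2 detectable members and red blood cell genes 0, too few for a median.

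The genotype differences of both cell types shared more genes than independent lists would. At least 2-fold lower in both were 37 genes against 7.59, and higher in both were 27 against 7.62, of 9857 genes. Opposite directions were taken by 15 and 11 genes, against 9.56 and 6.06. Both opposite directions thus also exceeded independent lists. Independent lists give every gene the same likelihood of passing 2-fold, while genes whose values vary more pass it more often in both pairs. They are thus too low a benchmark, and the excess over them overstates the sharing. The 64 same-way genes are better read beside the 26 opposite-way genes. Across genes, Pearson's r was 0.17. The arrays of a genotype can come from the same mice, which independent lists leave out, so differences between the mice could also give shared genes. Lower in both, beside Bhlha15, were Pik3r5, Tmem19, Polr2j, Gdf9, the glycolytic enzyme Aldoc, the secretory pathway gene Tmed6, the cysteine dioxygenase gene Cdo1, Tmem196, Erich4 and the ciliary GTPase gene Rab23. Tmed6 differed by -1.44 in zymogenic and -2.01 in neck cells, and Gdf9 by -2.36 and -1.79. Higher in both were Ifnar2 (1.59 and 1.86), Zfp84, Stox2 (2.17 and 1.39), Myef2, Selenoi, Zbtb11os1, Trim37, Abhd18, Slc24a5 and Cdc40. Many of these genes read close to or under the detection level in the lower arrays. With the pseudocount of 32, the counts were 8 lower and 4 higher, and the last 6 genes named here were under 2-fold in at least 1 cell type, as were Cdo1, Tmem196, Erich4 and Rab23.

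The additive limma model over all 4 arrays called 3 genes, all lower in MIST1-null mice. Pik3r5 differed by -3.81 ± 0.35 (SE), with a limma adjusted p of 0.00301. Tmem19 differed by -2.89, with a limma adjusted p of 0.00344, and Gm12888 by -2.49, with a limma adjusted p of 0.0138. Pik3r5 and Tmem19 read under the detection level in both MIST1-null arrays, so their sizes are not firm, and Pik3r5 was at -2.42 in zymogenic and -1.77 in neck cells with the pseudocount of 32. Bhlha15 itself differed by -2.17 ± 0.36, with a limma adjusted p of 0.104. The count moved from 1 to 158 genes over the alternatives, so it describes a model with 1 residual degree of freedom more than a set of genes. The arrays of a genotype can come from the same mice, 4 wild-type and 5 MIST1-null, so these errors and p-values hold no spread between pools of mice.

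The difference between the genotype effects, zymogenic minus neck, put 7 of 21 lists apart from random lists. Above lay parietal markers (0.85), oxidative phosphorylation genes (0.46), endocrine markers (0.78), fibroblast and smooth muscle markers (0.64) and immediate early and heat shock genes (0.72). Below lay mucous neck markers (-0.94) and cell cycle genes (-0.59). The immediate early call was lost under quantile normalization and with the 75th percentile filter. The MIST1-activated genes were at -0.66, at percentile 6.42, within random lists.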

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

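The tests on loss of MIST1 as a source of the parietal signal, on MIST1 acting mainly in zymogenic cells, and on the sex of the pooled mice were chosen after the results were seen. The grouping of probe sets by the Y chromosome was also made after values were seen.

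Some named genes went opposite ways by at least 2-fold in the genotype contrasts or in the cell type contrasts. The difference of their genotype effects, zymogenic minus neck, was 7.38 for Lgals7, 4.57 for Cd53, 3.71 for St6gal1, 3.0 for Mfsd8 and 2.25 for Cyp1b1. It was -4.05 for N4bp2, -3.19 for Hyls1, -3.08 for Trmt10b, -2.98 for Nsun7, -2.85 for Ckap2 and -2.52 for Aass. These differences were not tested, since each value is 1 array. Several rest on values under the detection level, such as 4.58 for Lgals7 and 6.3 for Cd53 in MIST1-null neck and 15.0 for St6gal1 in wild-type zymogenic cells, so their sizes are not firm. With the pseudocount of 32, Lgals7 was at 2.06 in zymogenic and -2.07 in neck cells. It read 304 in MIST1-null zymogenic cells. Squamous keratinocyte genes, listed after Lgals7 was seen and before their values were, had medians of 0.32 and -0.25 for genotype in zymogenic and neck cells, both within random lists, and 0.87 at percentile 99.9 for cell type in MIST1-null mice. The median difference of their genotype effects, zymogenic minus neck, was 0.69 at percentile 98.2, apart from random lists.

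Probe sets outside the main measurement carried differences too. Of 4224 detectable probe sets with no listed gene, 84 were at least 2-fold higher in both MIST1-null arrays, against 35.0 for independent lists, and 87 were lower in both, against 29.2. Of 876 detectable probe sets with several genes, 0 were higher in both and 30 were lower in both, against 2.98. Without a detection filter, 43 of 48 probe sets whose placed genes all lie on the Y chromosome were at least 2-fold lower in both MIST1-null arrays. So were 18 of 19 probe sets with mixed or unplaced genes, with medians of -2.97 in zymogenic and -2.58 in neck cells. Of 1554 whose placed genes lie off the Y chromosome, 41 were lower in both and 0 higher. These probe sets share genes and are not independent. Independent lists are also too low a benchmark where some probe sets vary more than others, and opposite directions were not counted here.

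The parietal marker signal in MIST1-null zymogenic cells could come from the dissection. The list median stayed at 0.98 or above under 3 other normalizations, which argues against a remaining scale difference between the deposited arrays. Their medians already lay close together, so these choices could move the list little, and any scaling made before deposit was not tested. A second list, of mitochondrial and receptor genes of parietal cells, had a median of 0.62, at percentile 99.9. More parietal RNA in the MIST1-null than in the wild-type zymogenic dissection would give such a rise. The list was added after the data were seen, in which oxidative phosphorylation genes were higher in this comparison (median 0.50, 15 of 15 above 0). A rise of its mitochondrial members was thus likely beforehand and is not separate support. Zymogenic cells also express these members, which carry the median. The receptors Hrh2 (-0.14), Chrm3 (-0.50) and Ptger3 (1.61) went both ways. The MIST1-null zymogenic array read 3955 for Atp4a and 1945 for Atp4b, yet 9 of 14 parietal markers were lower there than in MIST1-null neck cells, with Car2 at -1.36 and Slc9a4 at -1.17. A rise of parietal genes within zymogenic cells predicts the same median of 0.99 and cannot be told apart from it with these arrays.

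The larger count of genes in the zymogenic than in the neck genotype comparison may partly reflect spread between arrays. The ratio of counts was at least 2.54 under 3 other normalizations, which argues against a remaining scale difference between the deposited arrays. Any scaling made before deposit was not tested. Probe sets with no listed gene spread more in the zymogenic comparison as well, with a ratio of median absolute differences of 1.45, against 1.40 for genes. A noisier array would give this, although such probe sets can hold transcripts. For the share past 2-fold, the ratio was 1.54 for these probe sets and 2.42 for genes. These shares start from unlike levels, 17.8% and 4.29% in neck cells, so their ratios do not compare directly. MIST1 acting mainly in zymogenic cells stays open, since the MIST1-activated genes put the difference of effects at percentile 6.42 over 4 members, and at 1.83 with no filter on low values. Differences in mice, in dissection or in amplification between the pools were not tested.

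The Y-linked probe sets had medians of -1.96 in zymogenic and -1.90 in neck cells, at median intensities of 51.3 and 42.6 in the wild-type and 13.0 and 11.7 in the MIST1-null arrays. Fewer male mice in the MIST1-null pools would lower single-copy Y genes, yet the median over Eif2s3y, Kdm5d and Uty was 0.47, higher in the MIST1-null arrays. Genomic DNA in the wild-type samples would raise other gene families there. All 1554 probe sets of several genes off the Y chromosome had medians of -0.15 in zymogenic and -0.09 in neck cells. The test used the 752 of them at a mean level like that of most Y-linked ones. Averaged over both cell types, these had a median of -0.20 (bootstrap 95% CI -0.25 to -0.11 over 359 families). The rule set in advance took a median over -0.25 as against this explanation. The median met that rule, while its interval reached the bound. Among these 752 probe sets, 29 were lower by 2-fold in both and 0 higher, so this explanation stays open, and the design text states a DNase I treatment. A Y chromosome of another strain origin may also differ in copies, which was not tested, and a direct effect of genotype stays open.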

How the results depend on the processing

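All alternatives were chosen before the data were examined. Under quantile normalization, cyclic loess, median centring and the mean over probe sets, each count outside limma stayed within 1.5 times its reported value, no list called apart turned its sign in any alternative, and the other choices moved counts as follows. In the order genotype in zymogenic higher and lower, genotype in neck higher and lower, cell type in wild-type higher and lower, cell type in MIST1-null higher and lower, and genotype in both cell types lower and higher, the 3-fold threshold gave 112, 168, 32, 53, 206, 243, 216, 175, 8 and 2 genes, and the pseudocount of 32 gave 167, 180, 28, 54, 262, 315, 215, 222, 8 and 4. The 75th percentile filter gave 369, 347, 104, 120, 398 (wild-type higher only), 313, 348, 18 and 14. No filter gave 1167 for zymogenic lower, 333 and 556 for neck, 1166 for wild-type higher and 98 for both lower. Zymogenic-enriched and neck-enriched genes kept in MIST1-null mice were 37.9% and 29.6% at 3-fold, 36.3% and 32.7% with the pseudocount, 36.9% and 30.1% with the 75th percentile filter and 20.8% and 23.1% with no filter. Fewer or lower genes enter by construction with the filters and the threshold, and the pseudocount shrinks differences of dim genes. The limma count was 36 with quantile normalization, 60 with cyclic loess, 158 with median centring and 15 with the 75th percentile filter. It was 47 with the pseudocount, 7 with the mean over probe sets, 1 without the trend and 3 with no filter. The count rose in step with limma's prior degrees of freedom, the weight given to the variance shared over genes. These went from 6.41 without the trend to 185 with median centring, and why they differed was not tested. Of 116 values of named genes, the pseudocount moved 105 and left 100 past 2-fold, where 115 had been, and none turned its sign. Of 104 list values, 41 were apart, 28 of them in every alternative, and of the other 63, 12 were apart in at least 1 alternative. Of 13 lost in at least 1, the neck markers for genotype in zymogenic cells went to percentile 6.41 with the 75th percentile filter, and the metaplasia list there to 88.6 with that filter and 67.2 with no filter. The limma model with cell type as a term was the only fit of genotype across cell types. For genes with 2 detectable probe sets, these differed by a median of 0.35 log2 units in the zymogenic and 0.27 in the neck genotype comparison. The 95th percentile of that gap was 1.47 and 1.23, past 2-fold. Pearson's r between the 2 probe sets of a gene was only 0.30 and 0.20, which limits how far single genes can be read.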

Other observations

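Several gene groups outside the comparisons' leading lists gave values of interest. The Y-linked genes Eif2s3y, Kdm5d and Uty were detectable in all 4 arrays. Eif2s3y ranged from 223 to 450, Kdm5d from 87.2 to 144 and Uty from 64.9 to 129, and Xist stayed under the detection level, at 19.4 to 35.8. Of the surface mucous genes, Psca ranged from 4653 to 7299 and Gkn2 from 883 to 1619. Colipase, Clps, a pancreatic lipase cofactor, ranged from 7831 to 11106, while the pancreatic enzyme genes Cpa1 and Ctrb1 stayed between 34.7 and 74.5. The appetite hormone gene Ghrl ranged from 3214 to 6972. Cholesterol synthesis members went both ways in MIST1-null zymogenic cells, with Sqle at 1.92 and Idi1 at -0.79.

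Of the 64 genes past 2-fold the same way in both cell types, 0 were among the 100 placed genes nearest to Bhlha15 in the gene order of assembly GRCm38.p6, where 0.65 per 100 would be the average. Beside Bhlha15, 3 of them lay on its chromosome, which holds 6.08% of the genes placed. The Y-linked gene Srsy, chosen after its values were seen, differed by -1.67 in zymogenic and -1.63 in neck cells.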
